A study of Mus musculus with 8 samples.

How the data were processed

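Histone marks were mapped by CUT&RUN, in which an antibody directs a protein A-MNase fusion to the marked nucleosomes of permeabilised cells and the released DNA fragments are sequenced. The cells were haematopoietic stem cells (HSCs) sorted from mouse bone marrow by surface markers, from control mice (WT) and from mice in which the retinoid X receptor genes Rxra and Rxrb were deleted in blood cells by Vav-Cre (RXRKO). The labels of the WT samples and the design text disagree on whether the WT mice carried Vav-Cre, so any difference between genotypes may also hold a difference in Cre. The mice were about 10 months old, the cells of 4 or 5 mice were pooled, and 7500 HSCs went into each assay. The 8 libraries comprise H3K4me1 in 2 WT and 2 RXRKO libraries, H3K4me3 in 1 WT and 1 RXRKO library, and H3K27ac in 1 WT and 1 RXRKO library. The labels do not say whether the 2 replicates of a genotype came from separate pools of mice, so every p-value of a single gene measures the spread between libraries only. The p-values of gene lists compare the genes of a list with the other genes, at a preset or estimated correlation between genes. They do not measure the spread between mice either.

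The deposited files are peak lists, 1 per library. Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.7.1, aligned them to mm10 with Bowtie2 2.2.5 and called peaks with MACS3. The version of MACS3, the use of a control library, the handling of duplicate reads and any spike-in are not given in the sources used here. The coordinates are those of the deposited lists, printed here as 1-based inclusive positions on mm10. In the deposited lists the authors' score is 10 times the -log10 q of the peak cut to a whole number. The authors' fold is the ratio of the peak's height to the local background that the peak caller used. Whether that background came from the same library or from a control is not given. The deposited -log10 p and -log10 q values were also made by the authors' peak caller, and the lists hold peaks with q under about 0.05. These values describe or rank peaks within 1 list and were not compared between libraries as amounts of a mark. Where a cut on fold or -log10 q was applied to every list, a peak under the cut counts as absent.

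The lists give no read totals, so the sequencing depth is unknown and no counting intervals were computed. As a stand-in, the pileup at each summit and its local background were recovered from the authors' fold and -log10 p, and the most frequent background value was taken as the genome-wide background of the library. If a control library was used, this background may not follow the depth of the library itself. This background was 5.62 and 7.37 in WT H3K4me1 replicates 1 and 2, and 6.53 and 12.6 in RXRKO H3K4me1 replicates 1 and 2. It was 4.12 in WT H3K4me3, 6.68 in RXRKO H3K4me3, 4.77 in WT H3K27ac and 4.19 in RXRKO H3K27ac. The run tags in the peak names put both replicate 1 H3K4me1 libraries in one run and the other 6 libraries in another. The replicate number therefore marks a batch that holds both genotypes, and a fit with it as a block was run beside the fit without it. Over 17760 genes the difference between replicates in WT correlated with that in RXRKO with r = 0.212 across genes, which are not independent replicates.

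Gene positions came from an annotation of the same build with 21631 protein-coding genes on 20 chromosomes, which gives the lower and higher end of each gene but no strand, exon or transcript. The start of a gene was taken as the annotated end with more H3K4me3 within 2 kb, summed over both genotypes. The lower end was used for 7602 genes, the higher end for 7526, and both ends for the 6503 genes with a tie. This replaced the 5' end planned before the data were examined, and exon and intron positions were not used. A gene with no called promoter may have its used start away from its outermost annotated end.

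For H3K4me1, the base pairs covered by called peaks in the gene body plus 20 kb on each side were taken as log2 of the length plus 1000 bp and centred on each library's median. Genes with a mean covered length of at least 1000 bp were tested with limma 3.58.1 (lmFit, and eBayes with trend) without a block, and Benjamini-Hochberg adjusted p under 0.05 was called. Gene lists were tested with camera on the same fit with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 15 lists. Overlapping H3K4me1 peaks of the 4 libraries were merged, and regions were counted by the libraries that called them. For H3K4me3 and H3K27ac, a promoter was called when a peak overlapped the 1 kb on either side of the gene's start, by at least 1 bp. Distal H3K27ac regions were merged peaks lying more than 1 kb from any gene's start. With 1 library per genotype these marks allow no test. For each gene list, the median log2 difference in covered length was instead ranked among 10000 random lists of the same size and similar covered length, as a percentile that describes these libraries only. The window was 2 kb on either side of the start with 500 bp added for H3K4me3, and the gene body plus 20 kb with 1000 bp added for H3K27ac. All differences are RXRKO minus WT.

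The 15 gene lists hold 495 entries and 484 distinct genes, of which 482 are in the annotation. They cover HSC identity, quiescence and cell cycle brakes, the MYC family, MYC targets, RXR heterodimer targets, nuclear receptors, cell cycle genes, ribosomal proteins, interferon and inflammation, housekeeping genes, and genes silent in blood. Markers of other cells that the gate could hold form the remaining lists, namely granulocytes and monocytes, lymphocytes, erythroid cells and megakaryocytes, and stromal and endothelial cells. The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined. A further list of 30 mature neutrophil genes was written after the promoters called in RXRKO alone had been seen.

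The naming rule takes Rxra, Rxrb and the MYC family always. For H3K4me1 it takes the 10 smallest p-values per direction among genes that pass, or the next by p up to 5 when fewer than 5 pass. For promoters it takes the 10 with the highest -log10 q per direction among those with no call in the other genotype within 2 kb, and for distal H3K27ac the 5 regions with the highest -log10 q per direction. From each list it takes up to 4 members with the largest absolute difference, and the members with a promoter called in 1 genotype when they number 6 or fewer. Predicted genes and clustered paralogs recognised by name, such as olfactory receptor, vomeronasal receptor, keratin-associated, histone and protocadherin cluster genes, were passed over in the top lists. The protocadherin clusters were recognised as such only after the promoter lists had been seen, and the distal list was filtered by name only after its regions had been seen.

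The pipeline was tested on simulated data before use. In covered lengths simulated with the spread between the H3K4me1 replicates and with 200 of 17760 genes changed, limma recovered 86% of changes of 1.5-fold with 13 false calls, 99.5% of changes of 2-fold with 16 false calls, and 100% of changes of 3-fold with 12 false calls. Simulated genes of similar covered length had nearly the same spread, and no difference between runs was simulated. These shares may therefore be too high for the real data, where Olfm3 at 2.60-fold did not pass. Covered lengths were exact in 400 of 400 simulated windows. Alternatives covered the replicate block, added lengths of 200 and 5000 bp, no filter, no centring, quantile normalization, windows of 5 and 50 kb, peaks with -log10 q of at least 5, the same number of top peaks per library, limma without the trend, each library left out in turn, the overlap and merging of regions, promoter widths of 500 bp and 2 kb, and a stricter definition of absence. Peaks with a fold of at least 4, promoters at either gene end, and the RXR list without Pdk4 were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.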

Results

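The data are 8 lists of CUT&RUN peaks from sorted HSCs, the rare bone marrow cells that renew the blood system. H3K4me1, a mark of enhancers and promoter flanks, was mapped in 2 WT and 2 RXRKO libraries. H3K4me3, a mark of promoters, and H3K27ac, a mark of active promoters and enhancers, were each mapped in 1 WT and 1 RXRKO library, so neither has replicates. The H3K4me1 lists held 149377 and 159713 peaks over 112.5 and 117.8 Mb in WT replicates 1 and 2, and 147698 and 165128 peaks over 109.8 and 133.3 Mb in RXRKO replicates 1 and 2. The H3K4me3 lists held 47835 peaks over 45.5 Mb in WT and 58136 over 53.8 Mb in RXRKO, and the H3K27ac lists held 74287 peaks over 47.1 Mb in WT and 64849 over 44.6 Mb in RXRKO. The median of the authors' fold over background within a list ran from 3.31 in RXRKO H3K4me1 replicate 2 to 6.09 in WT H3K4me3. Read totals are not in the files, and the recovered background in RXRKO was 1.47 times that in WT for H3K4me1, 1.62 times for H3K4me3 and 0.879 times for H3K27ac. The share of covered bases that 2 H3K4me1 libraries had in common, over the bases covered in either, was 0.742 for WT and RXRKO replicate 1, 0.714 for the WT replicates, 0.708 for WT and RXRKO replicate 2, and 0.697 for the RXRKO replicates. Between genotypes this share was 0.754 for H3K4me3 and 0.585 for H3K27ac.

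The peaks over the deleted genes were examined first, since DNA that is missing from the cells can give no fragments for any mark. Rxrb, which encodes retinoid X receptor beta, lies on chromosome 17 from 34031812 to 34038403, and a stretch of 781 bp inside it, from 34033516 to 34034296, was covered in both WT H3K4me1 libraries and in none of the 4 RXRKO libraries. The WT H3K4me1 peaks ran from 34032906 to 34034296 in replicate 1 and from 34032903 to 34034306 in replicate 2, whereas the RXRKO peaks at the same place ended at 34033515 in both replicates. The RXRKO H3K4me3 peak ended at 34033497, and an RXRKO H3K27ac peak with no WT counterpart ended at 34033514. H3K4me1 covered 1391 and 1431 bp of Rxrb in the WT libraries and 580 and 738 bp in the RXRKO libraries. Rxra, which encodes retinoid X receptor alpha on chromosome 2 from 27676445 to 27763319, held 22 and 20 H3K4me1 peaks in WT and 19 and 20 in RXRKO, and its longest stretch covered in WT alone was 76 bp. A stretch of 340 bp in Rxra was covered in both RXRKO H3K4me1 libraries and in no WT library. H3K4me1 covered 24.8% and 28.1% of Rxra in the WT replicates. Missing DNA could lie where WT has no peak, so the peaks cannot show whether Rxra was deleted. No WT peak of H3K4me3 or H3K27ac reached the Rxrb stretch, so in those marks its absence in RXRKO carries no comparison. With peaks of a fold of at least 4 alone, the Rxrb stretch was 0 bp long. The WT H3K4me1 peaks over it had folds of 3.51 and 3.36, so this cut removed them whatever the RXRKO libraries held. This alternative therefore carries no comparison.

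**Figure D1:**
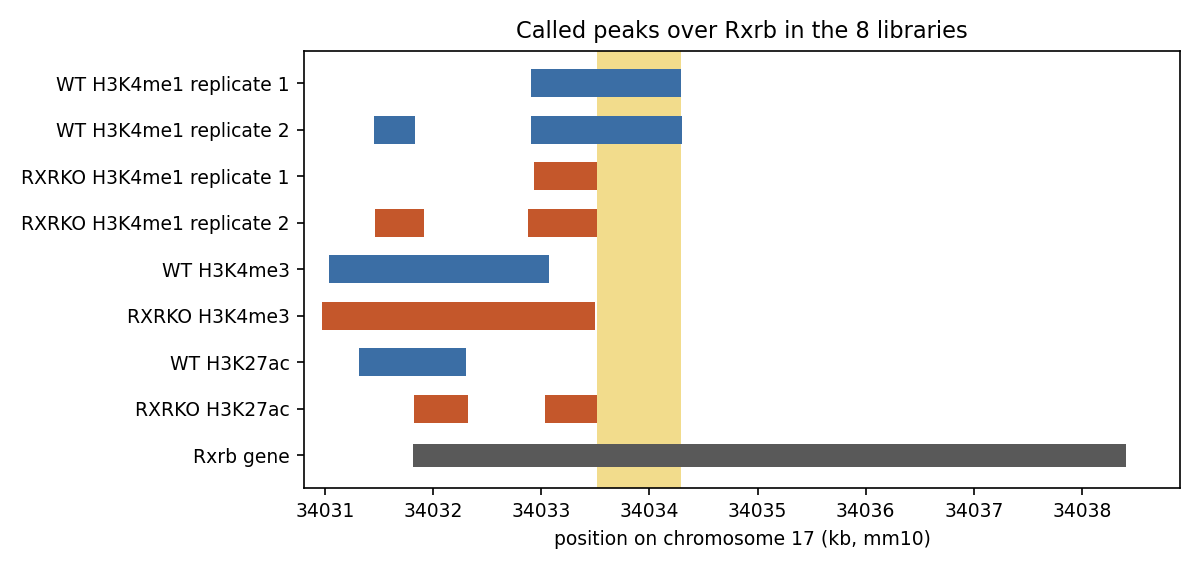
Called peaks (bars) over Rxrb in the 8 libraries, by position in kb on chromosome 17 (mm10), with the gene in grey and WT in blue and RXRKO in orange. The shaded stretch of 781 bp was covered in both WT H3K4me1 libraries and in no RXRKO library.

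The comparison of H3K4me1 between RXRKO and WT asks where loss of the receptors altered the enhancer landscape of HSCs. No gene passed the test for covered length. The genes with the smallest p-values and more H3K4me1 in RXRKO were Mlip, which encodes a lamin-interacting protein of muscle, Olfm3, which encodes an olfactomedin, Cep152, which encodes a centriole assembly scaffold, the ubiquitin ligase gene Marchf4, and the prohormone convertase gene Pcsk2. Those with less were Gria1, which encodes a glutamate receptor subunit, its auxiliary subunit gene Shisa9, Impg1 of the photoreceptor matrix, Larp7, which stabilises the 7SK RNA, and Sap30 of the SIN3 histone deacetylase complex. The log2 difference was +0.71 (SE 0.089) for Mlip (chromosome 9, 77102084 to 77352782), +1.38 (SE 0.198) for Olfm3, +0.66 (SE 0.0998) for Cep152, +0.84 (SE 0.134) for Marchf4 and +1.02 (SE 0.164) for Pcsk2, with 2 libraries per genotype. It was −0.70 (SE 0.0997) for Gria1 (chromosome 11, 57011571 to 57330244), −0.47 (SE 0.068) for Shisa9, −0.53 (SE 0.079) for Impg1, −0.67 (SE 0.106) for Larp7 and −0.60 (SE 0.096) for Sap30. Each of these 10 genes had an adjusted p of 0.124 in limma, the lowest over all genes, so none of them passed.

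Of 17760 genes tested with limma, 0 were higher and 0 were lower in RXRKO at an adjusted p under 0.05, and 1051 had an unadjusted p under 0.05. With the replicate number as a block, 2 genes rose and 0 fell, namely Cox7b2, a relative of a cytochrome c oxidase subunit (log2 +1.18, adjusted p = 0.0359), and Mlip (adjusted p = 0.0405). Grouping the same 4 libraries by replicate number gave 0 genes with 1434 at an unadjusted p under 0.05, and the crossed grouping gave 0 with 350. The count was 88 without WT replicate 1, 13 without WT replicate 2, 98 without RXRKO replicate 1 and 0 without RXRKO replicate 2, where the genotype with 1 library is assumed to vary like the other.

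Among the 15 gene lists, the RXR heterodimer targets fell in H3K4me1 relative to all genes. These are genes that RXR paired with retinoic acid, liver X, PPAR or vitamin D receptors is known to control. Of the 32 measured, 23 lay below 0 and 9 above, with a median log2 difference of −0.064 and a mean of −0.087 (camera on the limma fit, adjusted p = 0.00944, and 0.0129 with the replicate block). The adjusted p = 0.642 with an estimated correlation, so the call does not hold there. The largest difference was at Pdk4, which encodes a pyruvate dehydrogenase kinase and is a classic PPAR target. Its window had 3966 and 3805 bp of H3K4me1 in WT and 2088 and 1899 bp in RXRKO (log2 −0.77, SE 0.14), with an adjusted p of 0.133 over all genes and 0.00724 adjusted over the list alone. The retinoic acid hydroxylase genes Cyp26b1 (−0.26) and Cyp26a1 (−0.20) also lay toward the lower end, and neither passed. Without Pdk4 the adjusted p of the list was 0.0519, without WT replicate 2 it was 0.0818, and without RXRKO replicate 2 it was 0.121. The call also ended at -log10 q of at least 5 (adjusted p = 0.148), with the same number of peaks (0.0510) and with a 5 kb window (0.0530). With peaks of a fold of at least 4, an alternative chosen after seeing the data, the median turned to +0.0086 (adjusted p = 0.851). With no centring of the libraries the median was −0.0049 (adjusted p = 0.0169), and with a 50 kb window it was −0.028 (adjusted p = 0.0277).

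**Figure D2:**
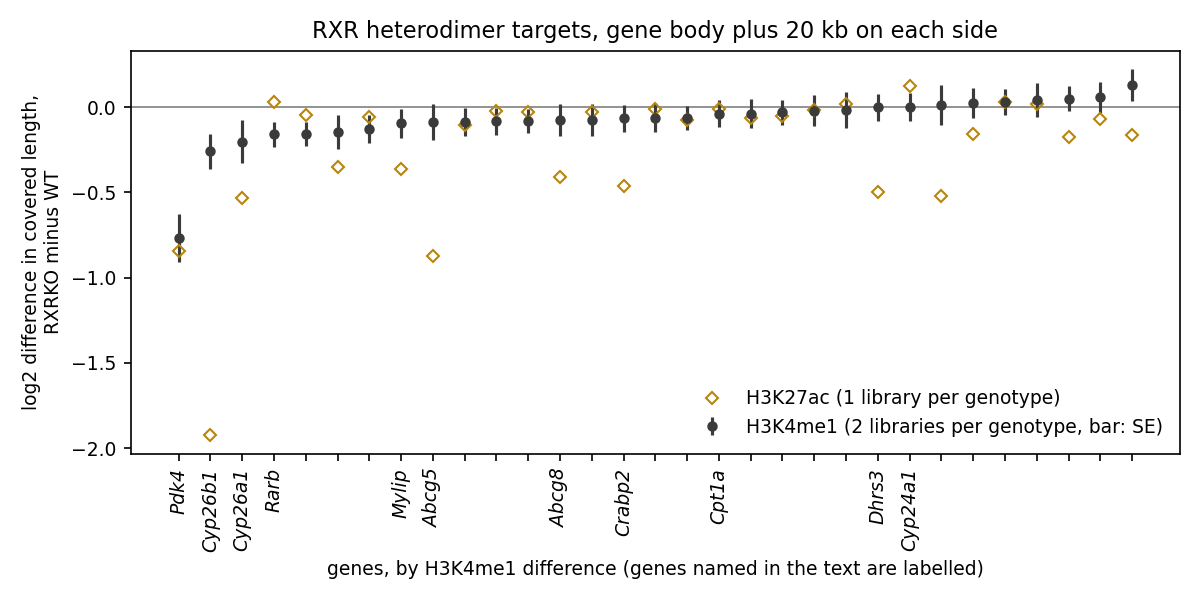
Log2 difference in covered length (RXRKO minus WT) for 31 of the 32 measured RXR heterodimer targets, over the gene body plus 20 kb on each side, with H3K4me1 as points with SE (2 libraries per genotype) and H3K27ac as open diamonds (1 library per genotype). H3K4me1 lies below 0 for 22 of the 31 genes drawn, with Pdk4 lowest at −0.77, and H3K27ac is lowest for Cyp26b1 at −1.92.

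At Pdk4 (chromosome 6, 5483351 to 5496278) the difference sat in an element 12546 bp from the gene, beyond the end that carries the H3K4me3 peak. WT H3K27ac was called there from 5508825 to 5510556 with a fold of 6.07, and WT H3K4me3 from 5509297 to 5510234 with a fold of 8.59, while neither RXRKO library called a peak. H3K4me1 ran from 5508554 to 5510694 and from 5508860 to 5510688 in the WT replicates, against short peaks from 5509511 to 5509813 and from 5509385 to 5509668 in the RXRKO replicates. The peak at the gene's start was called in all 8 libraries. The rules for list members and for distal H3K27ac both name this site, and the other marks at the element were looked at after those values were seen.

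**Figure D3:**
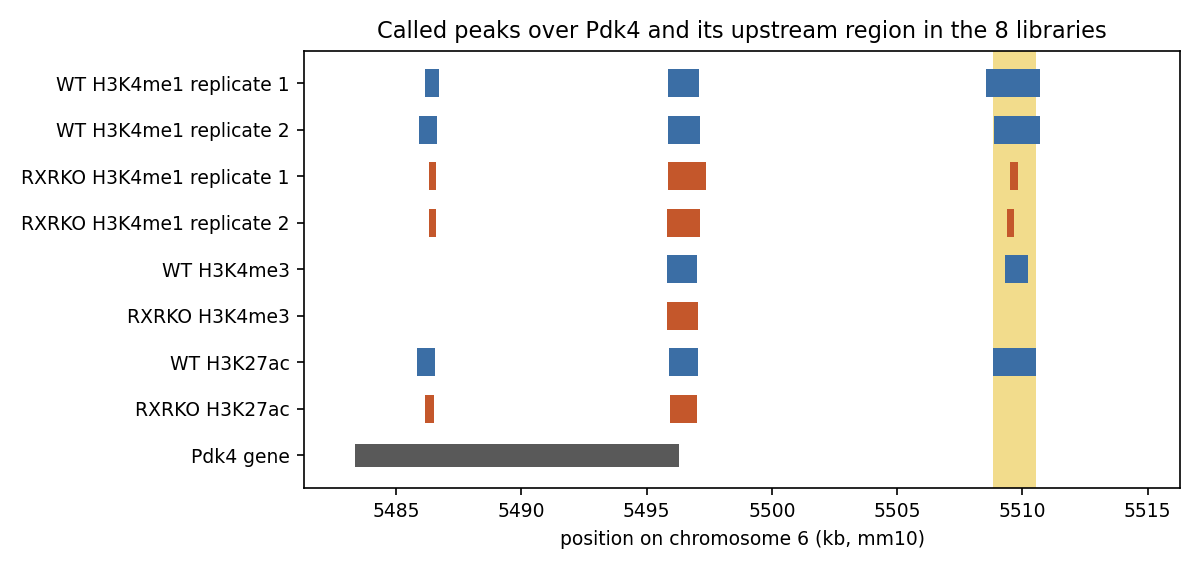
Called peaks (bars) over Pdk4 and the sequence beyond its H3K4me3-marked end in the 8 libraries, by position in kb on chromosome 6 (mm10), with the gene in grey, WT in blue and RXRKO in orange. The shaded element has H3K27ac and H3K4me3 peaks in WT alone, and its H3K4me1 peaks are shorter in both RXRKO libraries.

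The genes of the MYC pathway, which the series title names, showed no difference in H3K4me1 that passed. Myc itself, the transcription factor that drives growth and division (chromosome 15, 61985341 to 61990361), had a log2 difference of +0.03 (limma, adjusted p = 0.998). Among the other MYC family genes, Mxd4, which encodes a repressor that competes with MYC for its partner MAX, had the largest value at +0.18 (SE 0.09), followed by Mga at +0.10, Mlxip at +0.07 and Mycn at +0.07. The remaining members, Max, Mlx, Mlxipl, Mnt, Mxd1, Mxd3, Mxi1, Mycl and Zbtb17, lay between −0.07 and +0.04. The list had 10 of 14 members above 0 (adjusted p = 0.464). The MYC targets, genes of ribosome assembly and nucleotide metabolism, had 33 of 64 members above 0 (adjusted p = 0.506), with Nop58 at +0.33 and Odc1 at −0.23. In the MYC family and the MYC targets, 0 genes passed over all genes and 0 adjusted over the list alone, with 0 and 2 at an unadjusted p under 0.05.

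Stem cell and cell cycle lists also gave no call in H3K4me1. HSC identity genes had 21 of 35 members above 0 with a median of +0.012 and a mean of −0.0050, which differ in sign (adjusted p = 0.996). Tek, the receptor for angiopoietin that marks quiescent HSCs, stood at −0.36 (SE 0.08, 0.0531 adjusted over the list alone), against +0.28 for Procr, the endothelial protein C receptor gene, and +0.21 for the HSC marker Fgd5. Quiescence and cell cycle brakes had an adjusted p of 0.464, with the cyclin kinase inhibitor gene Cdkn1b at +0.24 and the forkhead factor gene Foxo1 at +0.20. Cell cycle genes also had 0.464, with the spindle checkpoint kinase gene Bub1 at +0.35. Nuclear receptors had 0.464 as well, and 1 member passed on its own list, the thyroid hormone receptor gene Thrb (−0.37, 0.00486 adjusted over the list alone), while Rxrb stood at −0.19 and Rxra at −0.03. The Rxrb window holds the stretch of 781 bp without RXRKO peaks, where missing DNA and a loss of H3K4me1 cannot be told apart. Ribosomal proteins, housekeeping genes, and interferon and inflammation each had an adjusted p of 0.464.

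Markers of other cells gave no list call in H3K4me1. Granulocyte and monocyte markers, lymphocyte markers, erythroid and megakaryocyte markers, and genes silent in blood each had an adjusted p of 0.442, and stromal and endothelial markers had 0.726. Adjusted over the list alone, 1 erythroid gene passed, Epb42 of the red cell membrane (+0.50), and so did 3 genes silent in blood, among them the kidney gene Umod (+0.52) and the synaptic gene Syt1 (+0.51). The remaining lists had 0 members that passed adjusted over the list alone. Over all genes tested, 0 members of any of the 15 lists passed, and from 0 to 5 members of a list had an unadjusted p under 0.05.

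Regions of H3K4me1 were next counted by the libraries that called them. Both RXRKO libraries and no WT library called 3926 regions, and both WT libraries and no RXRKO library called 3514, out of 181218 merged regions, of which 112071 were called in all 4. The 3 RXRKO regions with the highest -log10 q lay near Tmem33 (chromosome 5, 67184567 to 67185887), near Cep152 and inside Mast4, which encodes a microtubule-associated kinase. The 4 WT regions with the highest -log10 q lay in Scrg1 (chromosome 8, 57468109 to 57469319), near Impg1, near the acyl-CoA thioesterase gene Acot2 and in Rgsl1. Where these regions carried H3K27ac in 1 genotype, it was mostly the same genotype. Of the RXRKO regions, 289 had H3K27ac in RXRKO alone and 36 in WT alone, and of the WT regions 256 had it in WT alone and 25 in RXRKO alone. H3K4me3 was called in RXRKO alone on 98 of the RXRKO regions and in WT alone on 6, and on the WT regions in WT alone on 69 and in RXRKO alone on 18. The crossed pairs leaned too, toward the genotype of their replicate 2 library. Regions of WT replicate 1 and RXRKO replicate 2 had H3K27ac in RXRKO alone on 86 and in WT alone on 37. Regions of WT replicate 2 and RXRKO replicate 1 had H3K27ac in WT alone on 45 and in RXRKO alone on 9. The replicate 2 H3K4me1 libraries shared a run with the H3K27ac libraries, so the agreement between marks cannot be put down to genotype alone. The individual regions named here were picked by rank after the data were seen.

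The split by genotype held 7440 regions, against 8757 for the split by replicate number and 3500 for the crossed split, so the genotype count was below that of the batch. With a fold of at least 4 the order turned, with 5455 for genotype, 4556 for replicate number and 1518 for the crossed split. The lean between genotypes turned too, with 1079 regions in both RXRKO libraries alone and 4376 in both WT libraries alone. At this cut a region whose RXRKO peaks have a lower fold counts as absent in RXRKO. The cut kept 69484 and 73083 peaks in WT replicates 1 and 2, against 60816 and 61705 in RXRKO replicates 1 and 2. The 4376 regions therefore need not lack H3K4me1 calls in RXRKO. Within replicate 1 alone 12339 regions were called in RXRKO and 15999 in WT only, and within replicate 2 alone 26683 and 16309. The RXRKO and WT counts were 8183 and 12372 without WT replicate 1, 8320 and 8296 without WT replicate 2, 19985 and 6392 without RXRKO replicate 1, and 6886 and 8776 without RXRKO replicate 2, each more than 1.5 times the count from all 4.

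**Figure D4:**
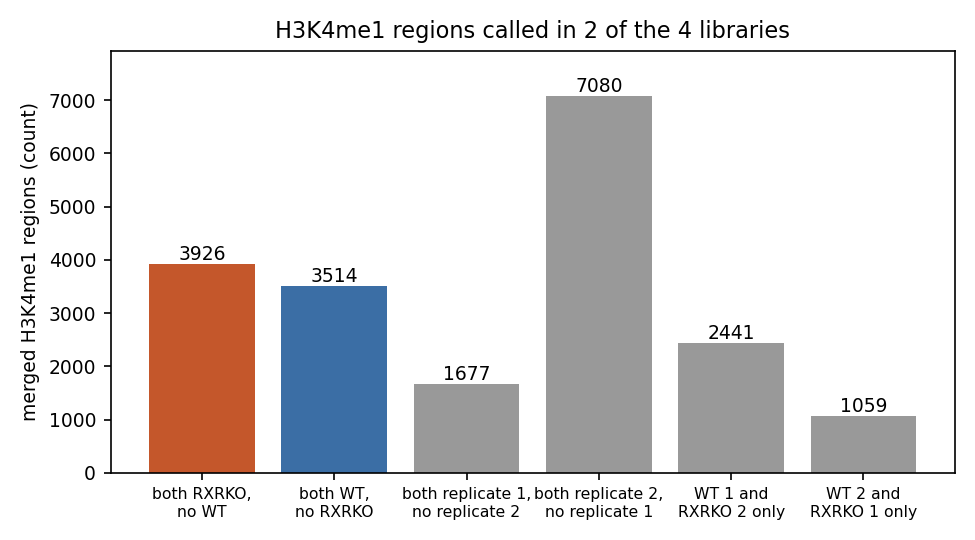
Number of merged H3K4me1 regions called in exactly 2 of the 4 libraries, by the pair that called them, with genotype pairs in colour and other pairs in grey. Both RXRKO libraries alone called 3926 regions and both WT libraries alone 3514, against 7080 for both replicate 2 libraries.

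H3K4me3 at promoters compares which genes carried the mark in each genotype. Of 21631 promoters, 14137 were called in both libraries, 291 in RXRKO only and 99 in WT only. The promoters called in RXRKO only with the highest -log10 q included Elavl2, a neuronal RNA-binding protein gene (chromosome 4, 91211533 to 91400108, fold 11.2), Gabrg1, a GABA receptor subunit gene (fold 9.62), Spock3, a brain proteoglycan gene (fold 9.78), Dpp6, which encodes a potassium channel partner (fold 9.18), and Rnf17, a germ cell gene (fold 9.63). The others of the 10 highest were the transporter gene Abca15, Crym, which encodes a thyroid hormone binding protein of the lens, the adhesion receptor gene Adgra1, the exchange factor gene Arhgef10l and Rassf9. Of these 10, Gabrg1, Spock3, Rnf17 and Dpp6 had H3K4me1 in RXRKO replicate 2 alone, and Elavl2 had it in both RXRKO libraries and WT replicate 1. Promoters called in WT only were led by Car6, a salivary carbonic anhydrase gene (fold 9.18), Umodl1 (fold 8.40), Klhl33, Tespa1, which acts in T cell receptor signalling, and the NOD-like receptor gene Nlrp10. After these came Slc17a8, a vesicular glutamate transporter gene, the sperm acrosome gene Spaca1, Lrrd1, the tight junction gene Cgnl1 and the dynein gene Dnah17. With the same number of top peaks in both libraries, the counts were 178 in RXRKO only and 167 in WT only.

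**Figure D5:**
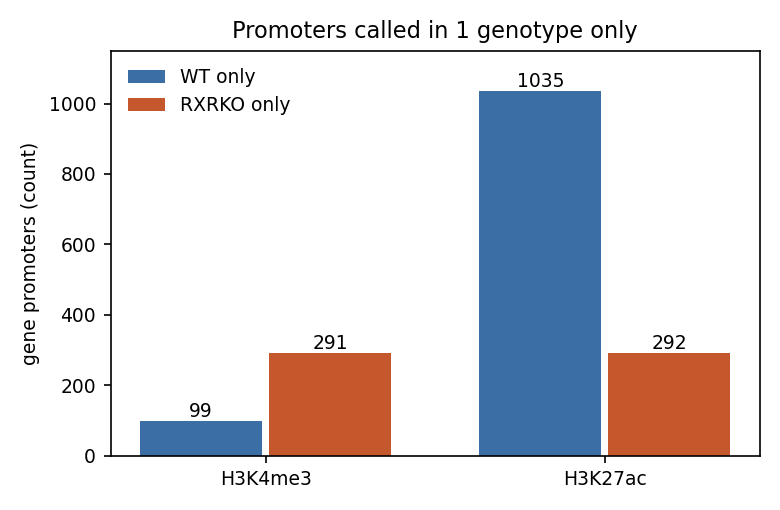
Number of gene promoters called in 1 genotype only, for H3K4me3 and H3K27ac, with 1 library per genotype and mark. H3K4me3 has 291 in RXRKO only and 99 in WT only, and H3K27ac has 292 in RXRKO only and 1035 in WT only.

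By list, H3K4me3 promoters of stem cell and MYC genes were called in both genotypes with few exceptions. All 14 MYC family promoters were called in both, as were 60 of 64 MYC targets, 34 of 35 HSC identity genes, 37 of 37 cell cycle genes, 35 of 36 quiescence genes, 31 of 33 nuclear receptors, 25 of 33 RXR heterodimer targets, 23 of 24 housekeeping genes and 28 of 31 interferon genes, with none in 1 genotype only. Myc had 2879 bp of H3K4me3 in WT and 2904 bp in RXRKO over its gene body. Promoters called in RXRKO only were the adult beta-globin gene Hbb-bt, the fractalkine receptor gene Cx3cr1, Cd79a of the B cell receptor, Lck, the kinase of T cell receptor signalling, the nephrin gene Nphs1, and Rpl22 of the large ribosomal subunit. The other ribosomal proteins (39 of 40), lymphocyte markers (16 of 33), granulocyte and monocyte markers (14 of 29), erythroid and megakaryocyte markers (22 of 30), stromal and endothelial markers (19 of 24) and genes silent in blood (15 of 30) were called in both, and no list had a promoter called in WT only.

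In covered length of H3K4me3, 2 of the 15 lists ranked in the lowest or highest 2.5% of random lists. These values are relative to all genes, whose own median shifted by +0.014. Cell cycle genes had less H3K4me3 in RXRKO on this scale, with 29 of 37 measured members lower and a median log2 difference of −0.026 (percentile 0.70), while 21 of the 37 were shorter in base pairs before this shift was taken off. The replication licensing gene Mcm3 was lowest (2120 bp in WT, 1568 bp in RXRKO). Erythroid and megakaryocyte markers had a median of +0.040 (percentile 98.1), with Hbb-bt at 0 bp in WT and 500 bp in RXRKO and the platelet glycoprotein gene Gp9 at +0.36. Genes silent in blood ranked at 95.9, with Nphs1 and the muscle factor gene Myog listed at 0 bp in WT, and at 100 at -log10 q of at least 5, 98.7 with a fold of at least 4 and 55.3 with the same number of top peaks. HSC identity ranked at 7.66, with the HSC factor gene Mecom at +0.36 and the ETS factor gene Fli1 at +0.33 at the upper end. RXR heterodimer targets ranked at 8.30, MYC targets at 13.6, interferon and inflammation at 27.2, and the MYC family at 30.3, where Mlxipl stood at +0.34 and Mxd3 at −0.14. Granulocyte and monocyte markers ranked at 39.3, ribosomal proteins at 40.3, lymphocyte markers at 49.1, nuclear receptors at 49.9, quiescence and cell cycle brakes at 52.6, housekeeping genes at 62.9, and stromal and endothelial markers at 86.7. Lengths summed over a list include everything called, and for cell cycle genes they were 68.5 kb in WT and 67.3 kb in RXRKO.

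H3K27ac at promoters went the other way in number. Of 21631 promoters, 11895 were called in both libraries, 292 in RXRKO only and 1035 in WT only. Promoters with H3K27ac in WT only were led by Lipo3 (chromosome 19, 33555160 to 33590669, fold 8.50), the adjacent genes Rnf224 and Slc34a3, a kidney phosphate transporter gene (1 peak, fold 6.52), the complement regulator gene Cd59b, Lyrm9, and Sos1, which encodes the exchange factor that activates RAS. They also included the potassium channel gene Kcnn3, Fam83f, the WNT receptor gene Fzd3 and Ogfrl1. Promoters with H3K27ac in RXRKO only were led by Sit1, which encodes an adaptor of T cell receptor signalling (chromosome 4, 43482083 to 43483709, fold 5.62), Smlr1, Eps8l1, an actin regulator gene, the neurotrophin gene Ntf3 and the tektin gene Tekt1. After these came Exoc3l2, Il1rapl1, Lrrn4cl, the recoverin gene Rcvrn and Bhlhe41, which encodes a circadian repressor. All 10 of the WT genes had H3K4me3 called in both genotypes. With no call in the other genotype within 2 kb, 814 promoters remained in WT only and 196 in RXRKO only. The median fold of their peaks in the calling library was 3.43 for WT and 3.47 for RXRKO. With the strictest definition of absence the counts were 467 in WT only and 78 in RXRKO only.

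Several stem cell regulators were among the promoters with H3K27ac in WT only. In the HSC identity list these were Cd34, Erg, Kit and Mllt3, of which Kit encodes the stem cell factor receptor used in the sort and Erg an ETS factor needed for HSC maintenance, against Prdm16 in RXRKO only and 20 of 35 in both. Among quiescence genes they included Cdkn1c, the p57 inhibitor gene that keeps HSCs out of division, and the Notch target gene Hes1, with 29 of 36 in both. The RXR heterodimer targets Abcg8, a sterol exporter gene controlled by liver X receptors, and Crabp2, a retinoic acid carrier gene, were called in WT only and the vitamin D target Cyp24a1 in RXRKO only, with 22 of 33 in both. Among lymphocyte markers, 6 promoters were called in WT only, those of Igll1, Ikzf3, Il7r, Rag1, Tbx21 and Tcf7, against 0 in RXRKO only and 12 of 33 in both. Cx3cr1 and the myeloperoxidase gene Mpo were called in WT only among granulocyte and monocyte markers (14 of 29 in both), and Gfi1b and Treml1 in WT only and Hbb-bt in RXRKO only among erythroid and megakaryocyte markers (18 of 30 in both). Further WT-only promoters included Ccnd2, Nr4a3, Rpl22, Sox17, Sox18, Tubb5, Alb, Krt5 and Pdx1. The MYC family had 13 of 14 promoters called in both, the MYC targets 60 of 64, cell cycle genes 35 of 37, ribosomal proteins 38 of 40, housekeeping genes 21 of 24, nuclear receptors 28 of 33, interferon genes 28 of 31, stromal and endothelial markers 14 of 24, and genes silent in blood 2 of 30. The peaks at Kit and Cd34 had a fold of 2.87, below the median of the WT list, 3.84.

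Distal H3K27ac was also called more often in WT in the full lists, but not with the same number of top peaks in both. Of 69368 distal regions, 41086 were called in both libraries, 18112 in WT only and 10170 in RXRKO only. The WT-only regions with the highest -log10 q lay in Tnpo1, the nuclear import receptor gene (chromosome 13, 98902396 to 98903253), at the Pdk4 element, 130243 bp from Tpra1, in the calcium channel gene Cacna1a and in Tmem51. Those in RXRKO only lay in Eml6 (chromosome 11, 29839616 to 29840266), in the teneurin gene Tenm2, in the phosphatase gene Mtmr10, in Jhy, and 266069 bp from the stress response gene Gadd45g. Inside single genes, most WT-only regions were counted in Foxp1 (30), a forkhead factor gene, Pde4d (25), the chromatin remodeller gene Arid1b (19), Aff3 (17) and the nuclear receptor gene Rora (16), and the genes with the most RXRKO-only regions included Celf2 (14), Fgf12 (12) and Msi2 (11), an RNA-binding regulator of HSCs. These counts grow with gene length, and the genes were picked by rank after the data were seen. H3K4me1 was called in all 4 libraries on 97.4% of the shared regions, 79.2% of the WT-only regions and 75.7% of the RXRKO-only regions. With the same number of top peaks in both libraries, the counts were 12436 in WT only and 12786 in RXRKO only, and with a fold of at least 4 they were 7976 and 5320.

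In covered length of H3K27ac around genes, RXR heterodimer targets had 27 of 32 measured members lower in RXRKO, with a median log2 difference of −0.075 (percentile 4.05) and 148.7 kb covered in WT against 123.1 kb in RXRKO. Cyp26b1 had 2991 bp in WT and was listed at 0 bp in RXRKO, the sterol exporter gene Abcg5 had 925 bp and 0 bp, Pdk4 had 3620 bp and 1448 bp, and Cyp26a1 had 1251 bp and 479 bp. The list ranked at 0 at -log10 q of at least 5, 0.74 with the same number of top peaks, 0.94 with 5000 bp added and 12.0 with a fold of at least 4. Genes silent in blood were the 1 list in the lowest or highest 2.5% (median −0.20, percentile 0.53), led by the cardiac gene Tnnt2 at −0.95, with Umod at +0.86, and with the same number of top peaks per library the median turned to +0.024 (percentile 62.7) and RXR heterodimer targets were the 1 list in these tails instead. HSC identity had a median of +0.029 (percentile 72.9) and 18 of 35 members higher, but the 4 with the largest differences were lower, namely Nkx2-3 (5500 bp in WT, 3193 bp in RXRKO), Hoxb4 (3925 bp, 2297 bp), Kit (6379 bp, 4072 bp) and Erg (11734 bp, 7789 bp). With a fold of at least 4 the list ranked at 0.42, and with the same number of top peaks at 97.2. Quiescence and cell cycle brakes ranked at 16.8, with the p21 gene Cdkn1a at −0.58 and the antiproliferative gene Tob1 at −0.54, but +0.52 for the neighbours Cdkn2a and Cdkn2b, which share a window. The MYC family ranked at 31.0, with Mycn at −0.42, Mga at +0.41, Mxd4 at −0.29 and Myc at −0.09, and the MYC targets at 5.42, with the methyltransferase gene Prmt3 at +0.90 and the licensing gene Mcm5 at −0.54. These values are relative to all genes, whose own median shifted by −0.073 between the libraries.

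The 4 lists of markers of other cells ranked from 4.79 to 78.8 in H3K27ac. Granulocyte and monocyte markers ranked at 5.81, with Mpo at 1094 bp in WT and 0 bp in RXRKO, and the neutrophil protease genes Elane and Prtn3, which share a window, at 2271 bp and 597 bp. Lymphocyte markers ranked at 7.12, with the B cell factor gene Pax5 at −0.67. Stromal and endothelial markers ranked at 4.79, with the niche chemokine gene Cxcl12 at −0.47, and erythroid and megakaryocyte markers at 78.8, with Treml1 at −0.69 and Hbb-bt at +0.49. Ribosomal proteins ranked at 18.5, cell cycle genes at 33.2, nuclear receptors at 63.6, housekeeping genes at 86.1 and interferon and inflammation at 89.7. Rxrb stood at +0.60 in this mark and the retinoic acid receptor gene Rara at −0.47. The Rxrb value includes the RXRKO peak that ends beside the stretch without RXRKO peaks, so it may not reflect a change in the mark. The medians of 10 of the 15 lists changed sign under at least 1 alternative, and those of RXR heterodimer targets, cell cycle genes, quiescence and cell cycle brakes, ribosomal proteins, and stromal and endothelial markers were below 0 under all that were run.

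The promoters called in 1 genotype only were compared between H3K4me3 and H3K27ac. Both marks were called in RXRKO only at 26 promoters, where 3.93 would be shared if the marks were independent, and in WT only at 20, where 4.74 would be. With no call in the other genotype within 2 kb, 12 RXRKO-only promoters remained, among them the Fc receptor gene Fcgr4, the inhibitory receptor gene Pirb, Ms4a6d, Rcvrn, Lrrn4cl and Smlr1. By the same definition 19 WT-only promoters were shared, among them Slamf7 and Cd52, surface proteins of lymphoid cells, the inflammasome gene Nlrp3, Ubash3a, Msi1, Klhl33 and Umodl1. Opposite calls also occurred, with H3K4me3 in RXRKO only and H3K27ac in WT only at 29 promoters against 13.9 if independent, and the reverse at 1 against 1.34. The numbers for independence are over all 21631 promoters, including those called in both genotypes or in neither. An excess over them can therefore arise without a shared difference, as the 29 opposite calls show. The H3K4me3 and H3K27ac libraries also shared a run, so the agreement cannot be put down to genotype. The genes in this paragraph other than Rcvrn, Lrrn4cl, Smlr1, Klhl33 and Umodl1 were chosen after their values were seen, and no test was run with 1 library per group.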

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

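Of the tests in this part, those with peaks of a fold of at least 4 and with a miss chance under 0.01 were chosen after the result was seen. The ratio of promoters called in RXRKO only to those called in WT only was 2.94 for H3K4me3 and 0.282 for H3K27ac, so the marks leaned in opposite directions in libraries from the same genotypes, and this difference was not tested, since each mark has 1 library per genotype.

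Sequencing depth could account for some of both imbalances, because the deeper library, by its recovered background, was RXRKO for H3K4me3 and WT for H3K27ac. For H3K27ac, depth as the whole cause is argued against: from the WT pileups and the RXRKO background, 185 misses are expected among the 1035 promoters called in WT only. That is a share of 0.179, with 84.5 of 292 in the other direction. WT-only promoters still outnumbered RXRKO-only ones by 1.95 times when both lists were held to the same number of peaks (813 and 417). With a fold of at least 4 the counts were 2030 in WT only and 445 in RXRKO only. The 2030 exceed the 1035 of the full lists, so some of these promoters had an RXRKO peak of a lower fold. That cut kept 33886 WT peaks and 29721 RXRKO peaks, so its counts add no separate argument. For H3K4me3 depth stays open: the expected misses were 64.6 of 291, a share of 0.222, below the bound set beforehand, but the same calculation gave only 2.51 of the 99 promoters in the other direction, so it leaves out other causes of missed calls, for H3K27ac too, and with the same number of peaks the imbalance was 178 against 167, and with a fold of at least 4 it was 322 against 221. Among promoters with a chance under 0.01 of being missed for depth, H3K4me3 had 89 in RXRKO only and 79 in WT only, and H3K27ac had 257 in WT only and 94 in RXRKO only. Differences between single preparations and the loss of RXR remain open for both marks, and 1 library per genotype cannot part them.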

How the results depend on the processing

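Peaks with a fold of at least 4, promoters and distal regions at either gene end, the block with an estimated correlation, the list without Pdk4 and all alternatives for the Rxrb stretch were chosen after seeing the data. Of 135 alternatives over 14 results, 81 kept the result within 1.5 times or on its side of the threshold, 44 moved a value or count, 8 ended a call and 2 reversed a direction. Only the RXR heterodimer targets could be scored as an ended call or a reversed direction. Each count was scored alone, so a lean between 2 counts that turned is not among these reversals. The leans of distal H3K27ac and of H3K4me1 regions did turn under some alternatives, as given below. Where no cause is named below, the cause was not tested. The number of genes called in H3K4me1, 0 in limma with 1051 at an unadjusted p under 0.05, was 2 with the replicate block, 204 with no filter on covered length, 65 with no centring (57 higher and 8 lower, with the median of all genes at +0.055), 2 at -log10 q of at least 5, and 0 to 98 with 1 library left out. The number of lists called in H3K4me1, 1, was 0 with an estimated correlation, with the block and an estimated correlation, with a 5 kb window, at -log10 q of at least 5, with the same number of peaks, and with a fold of at least 4 with or without the block, and 0 to 1 with 1 library left out. The RXR heterodimer targets' median of −0.064 stayed but lost its call with an estimated correlation (−0.064, adjusted p = 0.642) and with the block and an estimated correlation (−0.064, adjusted p = 0.639). It was −0.060 with a 5 kb window (adjusted p = 0.0530), −0.058 at -log10 q of at least 5 (0.148), −0.064 with the same number of peaks (0.0510), −0.062 without Pdk4 (0.0519), and −0.078 to −0.041 with 1 library left out. With no centring it was −0.0049 (0.0169) and with a 50 kb window −0.028 (0.0277), so the size depends on the centring and the window, and it reversed to 0.0086 with a fold of at least 4 (adjusted p = 0.851, and 0.925 with the block). Over all alternatives its adjusted p ran from 0.00663 to 0.925.

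Regions of H3K4me1 in both RXRKO libraries alone (3926) were 1079 with a fold of at least 4, 12339 and 26683 within replicates 1 and 2, and 6886 to 19985 with 1 library left out. Those in both WT libraries alone (3514) were 4376 with a fold of at least 4, which turns the lean to WT, 15999 and 16309 within replicates 1 and 2, and 6392 to 12372 with 1 library left out. The fold cut kept fewer H3K4me1 peaks in RXRKO than in WT, and a region with RXRKO peaks under it counts as absent. Within 1 replicate or with 1 library left out fewer libraries must agree, which raises the counts by construction. H3K4me3 promoters in RXRKO only (291) were 178 with the same number of peaks and 161 with the strict absence, which asks for -log10 q of at least 5 and no call within 2 kb, and 322 with a fold of at least 4, and those in WT only (99) were 167, 61 and 221. H3K27ac promoters in RXRKO only (292) were 78 with the strict absence and 445 with a fold of at least 4, and those in WT only (1035) were 467 and 2030. Distal H3K27ac regions in RXRKO only (10170) were 6645 at -log10 q of at least 5 and 5320 with a fold of at least 4, and those in WT only (18112) were 13496 and 7976. With the same number of peaks they were 12786 in RXRKO only and 12436 in WT only, so the excess in WT was gone. Lists in the lowest or highest 2.5% for H3K4me3 (2) were 3 at -log10 q of at least 5 and 3 with a fold of at least 4, where genes silent in blood joined. Those for H3K27ac (1, genes silent in blood) were 2 at -log10 q of at least 5 (RXR heterodimer targets, and quiescence and cell cycle brakes) and 2 with a fold of at least 4 (HSC identity, and stromal and endothelial markers). RXR heterodimer targets were the 1 list with the same number of peaks and with 5000 bp added. The Rxrb stretch (781 bp) was 0 bp with a fold of at least 4, a cut that removes the WT peaks that define it, and 781 to 791 bp with 1 library left out. Starts of annotated transcripts were not in the annotation, so that alternative was not run. The unknown read depth limits the promoter and region counts, since a peak missed in a shallower library counts as absent.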

Other observations

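In this part, the counts of regions around gene lists, the comparisons with peaks of a fold of at least 4, the matching of random lists on covered length, and all neutrophil tests were chosen after the results were seen. H3K4me1 regions called in 1 genotype were counted in the windows of the 15 gene lists and ranked among 10000 random lists of genes with similar covered length, which gave 30 percentiles. The windows of 32 RXR heterodimer targets held 18 regions called in both WT libraries and no RXRKO library, against a median of 8 in random lists, and 4 called in both RXRKO libraries alone, against 8 (percentile 5.82, but 26.7 at -log10 q of at least 5 and 32.0 with the same number of peaks). Rarb, the retinoic acid receptor gene that retinoids induce, held 4 of the 18, and the retinaldehyde reductase gene Dhrs3, the retinoic acid hydroxylase gene Cyp26b1, the ubiquitin ligase gene Mylip, which liver X receptors induce, and Cpt1a held 2 each. The WT percentile was 99.4 without Rarb, 98.3 with the same number of peaks (90.7 without Mylip, which led there) and 96.7 at -log10 q of at least 5 (84.7 without Dhrs3, which led there).

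Lymphocyte markers leaned the same way, with 15 regions in WT alone, of which 12 were distinct, against 5 in random lists (percentile 99.9), and 2 in RXRKO alone against 7 (percentile 2.2). The WT regions lay around Rag1 and Rag2, the recombinase genes, Ebf1 of the B lineage, Dntt, the CD3 genes Cd3d, Cd3e and Cd3g, Flt3, Lck, Ikzf3, Cd79b and Il2rb. At -log10 q of at least 5 the WT percentile was 78.3 and the RXRKO percentile 18.4, with a fold of at least 4 they were 47.2 and 64.9, and with the same number of peaks the RXRKO percentile was 8.4, so neither lean held throughout. HSC identity genes leaned to RXRKO, with 41 regions against 23 (percentile 99.9), led by Mecom (7), Fgd5 (4), Etv6 (4) and Meis1 (4), all known regulators or markers of HSCs. They held 27 in WT alone against 20 (percentile 89.1). Without Mecom the RXRKO percentile was 99.1, and with a fold of at least 4, where 1 region was left, it was 5.07.

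The lower H3K4me1 at RXR heterodimer targets may reflect the loss of the receptors, and the WT-only regions around these genes lay at percentile 99.8, but this fell to 96.7 at -log10 q of at least 5 and to 83.3 with a fold of at least 4, and these regions come from the same peaks as the covered length, so they cannot favour the genotype over depth. Pdk4 is a candidate source of the list's call, since without it the adjusted p was 0.0519, while 22 of the other 31 genes still lay below 0 with a median of −0.062. Depth stays open too: the deeper RXRKO library minus the shallower had a list mean of −0.035 (SE 0.025 over genes), against −0.087 (SE 0.028) for RXRKO minus WT. The deeper WT library minus the shallower had a mean of +0.019 (SE 0.021), of the opposite sign. Both contrasts within a genotype also cross the 2 runs. The distance of 0.0515 just passed the bound set beforehand, 2 SE of the first mean, a result against depth. That SE leaves out the spread of the second mean. The distance is 1.75 over the SE of the difference paired by gene and 1.37 over the combined SE of both. By these wider SEs, depth and genotype cannot be told apart here. For RXRKO minus WT, the list mean was −0.060 (SE 0.029) within replicate 1 and −0.114 (SE 0.033) within replicate 2.

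Mature neutrophil genes had longer H3K4me3 in RXRKO, with 10 of 14 measured genes higher, a median log2 difference of +0.33 (percentile 99.97) and 10.2 kb covered in WT against 13.96 kb in RXRKO. Since the list was written after some members had been seen, the 5 genes with a promoter called in RXRKO only were also left out, and the other 9 measured had a median of +0.13 (percentile 97.9), and of +0.011 with a fold of at least 4 (percentile 47.6). Promoters were called in RXRKO only at genes that included Cxcr2 and Fcgr4 for H3K4me3 and Cxcr2, Fcgr4 and Slpi for H3K27ac, and in WT only at Mmp8, while 10 of the 30 genes had H3K4me3 and 8 had H3K27ac in both. Of the 30, 8 are on other lists. H3K27ac lay at percentile 91.4, 99.2 at -log10 q of at least 5 and 98.7 with a fold of at least 4, and in H3K4me1 13 genes lay above 0 and 14 below (adjusted p = 0.889).

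Neutrophils among the RXRKO cells might be a source of the longer H3K4me3, although the sort for lineage-negative cells would remove them. Of 6 genes taken as the most abundant in neutrophils, S100a8, S100a9, Camp, Ngp, Lcn2 and Retnlg, 0 had H3K4me3 called within 2 kb in RXRKO. This argues against a large share of neutrophils only if mature neutrophils carry the mark at these genes. The data hold no neutrophil library that could show it. A small share need not give a called peak at these genes, so the test cannot exclude it. Greater depth of the RXRKO H3K4me3 library stays open: with the same number of peaks in both libraries the 9 genes lay at percentile 99.2, against 47.6 with a fold of at least 4, and the higher percentiles of the whole list (100 and 97.9) rest on genes that prompted it. A difference between the 2 single preparations and an effect of the genotype were not tested and remain open.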
